A study of Mus musculus with 5 samples.

How the data were processed

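The study measured RNA from N18 cells, a mouse neuroblastoma line, after infection with an adenovirus carrying the Dyrk1a coding sequence or with a control adenovirus vector. Per the labels, total RNA was extracted with Trizol and each of the 5 arrays, Agilent two-colour whole mouse genome arrays, set 1 Dyrk1a sample against 1 control vector sample. Dyrk1a RNA carried Cy5 on replicates 1, 2 and 3 and Cy3 on replicates 4 and 5. The series' design text calls the 5 measurements independent samples, so the spread between arrays was read as spread between separate samples plus array noise. How the arrays were scanned, background-corrected and normalized is not given in the sources used here.

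The values analysed were the authors' deposited log2 ratios, 1 table of 44290 features in 5 columns. The table held 0 columns of other samples. Neither the log base nor the direction of the ratio was stated. The base was inferred from the deposited values. Base 10 would turn the lowest value, -4.2, into a 15849-fold ratio. Extreme values of this kind recurred in sets of 27 to 30 unnamed features, grouped by like values and assumed to be replicate spots. Their SD of at most 0.054 follows partly from that grouping. The deposited values were therefore read as log2. A natural log was not excluded and would multiply each log2 value printed here by 1.44, without changing any p-value or sign. The median of the deposited log2 ratios was 0.017, 0.023, 0.019, -0.020 and -0.016 in replicates 1 to 5, so the columns were close to centred. Whether the submitters centred them is not given in the sources used here.

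The direction was settled from the values and the dyes. The probe of the Dyrk1a reference transcript was above 0 in all 5 columns, where ratios of Cy5 over Cy3 left unturned would have put it on opposite sides of 0 in the 2 orientations. Among unnamed features, 7 sets of tightly grouped values were found without regard to sign and assumed to be replicate control spots. In 6 of them replicates 1 to 3 had one sign and replicates 4 and 5 the other, and in the last, replicate 3, at 0.141, had the sign of the swapped arrays. The columns of the swapped arrays were read as turned before deposit, mainly from the Dyrk1a probe, and every column was used as Dyrk1a over control vector. Intensities were not used here, so no filter on dim probes could be run and the share of weakly expressed genes among those tested is unknown.

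Of the 44290 features, 32042 named 1 gene in the platform annotation, 47 named several and 12201 were unnamed here, control spots among them. For 31906 of the 32042 probes the Entrez identifier matched a gene table of assembly GRCm38.p6, which was used for names and for the order of genes along the chromosomes only. Blank values left 30948, 31001, 28711, 29839 and 28236 measured features in replicates 1 to 5. The reason for the blanks is not given in the sources used here. A gene's value in an array was the mean of its probes measured in all 5 arrays. This gave 11191 of the 19087 genes on the array. Of these, 4211 had 2 or more such probes. For 14 of the named genes 16 further probes lacked a value in some array and stayed outside the fit, and 5 of these probes had a mean of the opposite sign to the gene's change, in Cdk1, Dyrk1a, Lgr5, Pcdhga7 and Pmp22. Another 3116 features that name no gene or several were tested beside them, 14307 in all. Each array was centred on its median over the tested features, which removed 0.028, 0.051, 0.025, -0.027 and -0.021.

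Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided). The model had the Dyrk1a effect and a gene-specific dye effect as coefficients, because 3 arrays of 1 orientation against 2 of the other do not cancel a dye effect. This left 3 residual degrees of freedom and 2.87 prior ones. P-values were adjusted by the Benjamini-Hochberg method over the 14307 features, and an adjusted p under 0.05 was called. Standard errors (SE) and 95% intervals are those of the moderated fit. The number of arrays limits the precision. Python 3.11.15 with pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 prepared the table and drew the plots.

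25 gene lists and the rule for the genes named were fixed before the data were examined, the lists from general knowledge. They cover the REST complex, the SWI/SNF complex, REST-repressed neuronal genes, neuronal cytoskeleton and growth cone, neuroblast transmitter genes, clustered protocadherins, G1/S and DNA replication, G2/M and mitosis, D-type cyclins and CDK inhibitors, p53 targets, interferon response, calcineurin-NFAT, immediate early genes, unfolded protein response, heat shock, cholesterol synthesis, Notch, hedgehog and Wnt targets, the DYRK family, mouse orthologs of human chromosome 21 genes, SR splicing factors, oxidative phosphorylation, cytosolic ribosomal proteins, and markers of glia, fibroblasts with smooth muscle, and immune cells. Each list was tested with limma's camera, which asks whether members moved more than other genes, at the preset correlation of 0.01 between members and again with an estimated correlation. It was also tested with limma's fry, which asks whether a list's members moved on balance in 1 direction, or, as its mixed test, in either direction, without comparing them with other genes. With an estimated correlation camera takes its degrees of freedom from the 3 residual ones, which limits what can pass. P-values were adjusted over the 25 lists. Member counts are given over all features and adjusted over the list alone.

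The rule takes Dyrk1a and up to 12 genes per direction past the threshold with the same direction in all 5 arrays. Where fewer than 6 passed, the direction was filled up to 6 with the smallest p among genes of that direction in all 5 arrays. From each list it takes up to 4 members past the threshold, or, with none past it, the 2 members with the smallest p as values only. Any member of the REST complex could be named. 58 genes were named in this way, and a gene named outside the rule is said to have been chosen after its values were seen.

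Neighbouring genes were compared by the share of adjacent pairs whose changes had the same sign, against 10000 random orders of the genes (a permutation test, one-sided). Alternatives to these settings were no dye term, no centring, scaling or quantile normalization between arrays, array weights, leaving out each array in turn, probes tested singly, features measured in at least 4 arrays, robust or no moderation, other thresholds, genes with a symbol only, and the swapped arrays turned back. Averaging whichever probes were measured, reading the values as log10, leaving Dyrk1a out of its lists in camera and fry, the list tests without replicate 2, camera with an estimated correlation without each other array and with array weights, fry's mixed test without each array, the list tests on the dye term, and leaving out arrays in the dye and neighbour results were added after seeing the data.

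The fit was tested on simulated data for this comparison, 14307 features of which 200 single features and a list of 40 genes carried a known change, with the dye effects estimated from the real arrays. 2 models of the noise were used, and the second was chosen after the output of the first had been seen. In the first, each array's spread came from the residuals of the fit. With all 5 arrays 29.9%, 61.2% and 89.4% of the features changed by 0.25, 0.5 and 1 on the log2 scale were called, and without replicate 2 13.4%, 53.7% and 86.4%. In all 137 features were called with 5 arrays and 117 without replicate 2, of which 14 and 6 belonged to the list, lowered by 0.25, and 3 and 9 were unchanged ones. In the second, each array's spread came from its array weight, because residuals of so few arrays carry part of 1 array's noise into the others. The shares were then 35.8%, 92.5% and 98.5% with all 5 arrays and 98.5%, 98.5% and 100% without replicate 2, with 165 and 245 features called, 13 and 38 of them in the list and 1 and 9 unchanged. The models thus differ in whether leaving out replicate 2 raises the number of calls, and neither is used as evidence on that array. The list was recovered by camera among 11191 genes under both models. Of 100 random lists, 0 under the first model and 2 under the second had a camera p under 0.05 with all 5 arrays. Noise was drawn independently for each gene, while the estimated correlation was 0.0453 in the real mitosis list and 0.0708 in the replication list. The simulation therefore cannot show how camera behaves where members are correlated.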

Results

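The effect of added DYRK1A, a protein kinase encoded on human chromosome 21, was measured in N18 mouse neuroblastoma cells. Cells infected with a Dyrk1a adenovirus were compared with cells infected with a control adenovirus vector on 5 two-colour arrays, 3 with Dyrk1a RNA in Cy5 and 2 with it in Cy3. The arrays gave a value for 63.8% to 70.0% of 44290 features, and 11191 genes with a value on all 5 arrays were tested. All changes are log2 ratios of Dyrk1a over control vector, in a log base inferred from the values.

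Dyrk1a itself was the gene with the largest change. Its reference transcript probe had centred log2 ratios of 2.46, 2.30, 1.93, 3.02 and 2.37 in replicates 1 to 5. These averaged 2.42 ± 0.39 (SD, n = 5), higher in 5 of 5 arrays. The fitted log2 change was 2.46 (SE 0.12, 95% interval 2.17 to 2.75), a 5.52-fold rise with an adjusted p of 0.0139 in limma. A pair of other Dyrk1a probes, each missing from at least 1 array and so outside the fit, stayed near 0, with means of 0.066 over 2 arrays and -0.039 over 4. Where these probes lie relative to the coding sequence carried by the virus is not known here, so they need not detect its transcript. Averaging whichever Dyrk1a probes were measured gave 1.16 (limma adjusted p = 0.0266), an alternative chosen after seeing the data. Without replicate 1, 4 or 5 the limma adjusted p was 0.335, 0.0976 or 0.0510, so the call was lost each time. The fitted change stayed at 2.41 without replicate 1 and 2.30 without replicate 4. Without replicate 5 it was 1.29, because a further Dyrk1a probe, measured in the other 4 arrays, then entered the mean. That lost call cannot be put down to the value in replicate 5.

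Over all genes, the question was which transcripts differed when Dyrk1a was added. Other than Dyrk1a, none of the genes named for the smallest p in each direction passed the threshold. Traip, a ubiquitin ligase acting at the replication fork, had a log2 ratio of -0.46 (SE 0.040). Lmnb1, which encodes lamin B1 of the nuclear lamina, was at -0.42 (SE 0.038), and the kinetochore gene Nsl1 at -0.43 (SE 0.040). Fanca, a Fanconi anaemia DNA repair gene, was at -0.40 (SE 0.037), the cohesin acetyltransferase gene Esco2 at -0.37 (SE 0.034) and the clamp loader gene Chtf18 at -0.34 (SE 0.033). Without replicate 2 Fanca was at -0.20, where a further probe with a mean of -0.018 over the other 4 arrays entered its mean. Each of these 6 genes was below 0 in 5 of 5 arrays with a limma adjusted p of 0.0605. In the other direction, Ndrg4, of the N-myc downstream regulated family, had a log2 ratio of 0.51 (SE 0.047) with the same adjusted p. Its level also followed the dye, with a dye effect of 0.30 (limma adjusted p = 0.0351), and its values ran from 0.19 to 0.95. A second Ndrg4 probe, outside the fit, had deposited values of 0.193, 0.265 and -0.38 in replicates 1, 2 and 4. The ectonucleotidase gene Entpd3 was at 0.27, Pbxip1 at 0.26, the brain aldolase gene Aldoc at 0.30, from probes with means of 0.060 and 0.574, and the actin-associated gene Pdlim3 at 0.26, with limma adjusted p from 0.0724 to 0.0805 and values above 0 in 5 of 5 arrays.

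**Figure D1:**
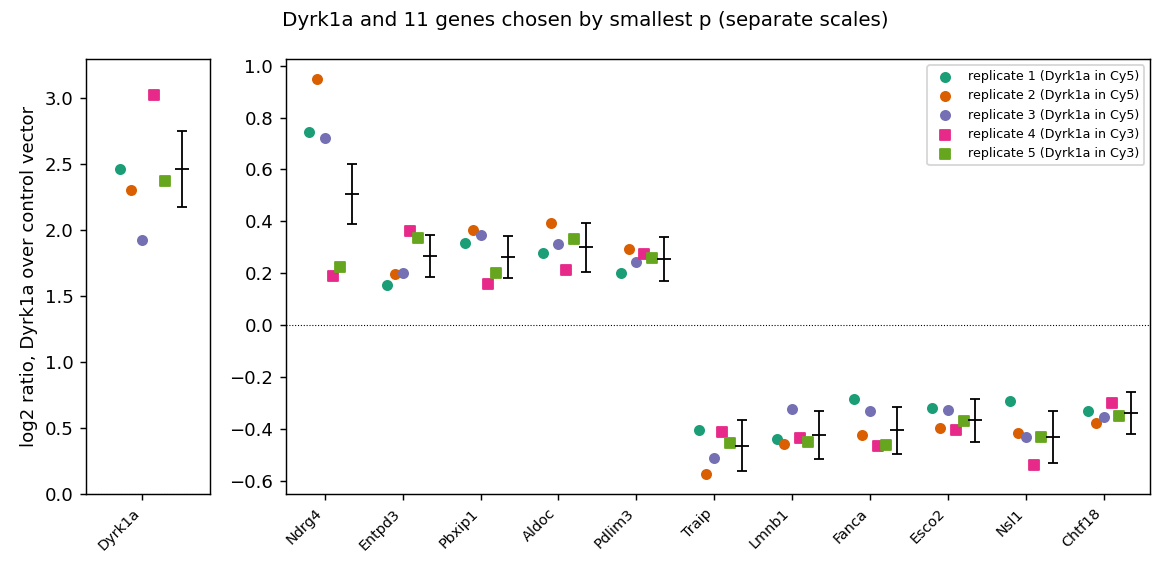
Log2 ratio of Dyrk1a over control vector (vertical axes, separate scales) for Dyrk1a and the 11 genes filled in by smallest p; each point is 1 array (circles with Dyrk1a in Cy5, squares with Dyrk1a in Cy3), and the black bar is the fitted change with its 95% interval. Dyrk1a lies between 1.93 and 3.02, Ndrg4 splits by dye orientation, and the 6 lower genes lie below 0 in all 5 arrays.

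In the limma fit 1 gene rose, Dyrk1a, and 0 fell. A further 114 genes had an adjusted p between 0.05 and 0.10, of which 14 were higher and 100 lower. At an unadjusted p under 0.05 there were 1301 genes, 587 higher and 714 lower, against 560 that chance would give. Of the 14 other groupings of the arrays' signs, 1 gave more, 3329 genes, and the rest gave 34 to 777. The sign was the same in all 5 arrays for 1458 genes, 13.0% of those tested. Of the 16 possible patterns of signs, a larger share of genes had the one that follows the dye orientation, 16.7%, and that one with replicate 2 turned, 14.2%. The count depended on 1 array. Replicate 2 had an interquartile range over genes of 0.288, against 0.145 to 0.166 in the other arrays, and without it limma called 81 genes higher and 248 lower. Scaling the arrays to the same spread gave 43 higher and 175 lower, quantile normalization 47 and 190, and array weights 622 and 717. The weights, estimated from these same arrays, were 3.74, 0.15, 0.58, 1.76 and 1.76 in replicates 1 to 5. Among the arrays with Dyrk1a in Cy5, replicate 1 therefore dominated that fit.

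The lists of dividing-cell genes were lower with Dyrk1a. Of 37 tested genes of G2/M and mitosis, 37 had a fitted log2 ratio below 0, with a median of -0.27, a 1.20-fold lower level, and 31 were below 0 in all 5 arrays. Aurkb, the Aurora B kinase of chromosome segregation, was at -0.36 (SE 0.038), and Cdk1, the kinase that drives entry into mitosis, at -0.30 (SE 0.032). A second Cdk1 probe, outside the fit, had deposited values of 0.117, 0.116 and 0.139 in the 3 arrays that measured it, above 0 where the fitted probe was below. Over all genes 0 of the 37 passed the threshold, while adjusted over the list alone 33 fell. Of 40 tested genes of G1/S and DNA replication, 39 were below 0, with a median of -0.25, a 1.19-fold lower level. Cdt1, which licenses replication origins, was at -0.33 (SE 0.035) and the cell-cycle transcription factor gene E2f2 at -0.35 (SE 0.039). Here 0 passed over all genes and 31 fell adjusted over the list alone. Camera gave adjusted p of 3.03e-36 for mitosis and 1.69e-31 for replication. The calls were lost at adjusted p = 0.0666 and adjusted p = 0.0675 with an estimated correlation. Fry, testing a balance in 1 direction, gave an adjusted p of 0.00457 for each. With Dyrk1a taken out of the lists that hold it, fry's adjusted p without replicate 4 or 5 was 0.0523 or 0.0666 for replication. For mitosis it was 0.0027 or 0.000647 in that setting. Without replicate 2, limma called 28 of the mitosis genes and 29 of the replication genes lower over all genes.

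D-type cyclins and CDK inhibitors, a list that also holds DREAM complex genes, were lower by a smaller amount. The median over 18 tested genes was -0.054, 13 of them were below 0, and camera's adjusted p was 0.00797 (adjusted p = 0.277 with an estimated correlation). Fry's adjusted p was 0.0634, and its mixed test for a change in either direction gave 0.0281, and 0.0572 to 0.75 without replicates 1, 3, 4 or 5. Lin54, at -0.28, Lin9 and Rbl1, at -0.19, fell adjusted over the list alone, and 0 passed over all genes. Lin9 was named after its values were seen. Lin54 and Lin9 encode subunits of the DREAM complex, which represses cell-cycle genes, and Rbl1 encodes the pocket protein p107. The list did not pass over features measured in at least 4 arrays, with a median of -0.024, or without replicate 5, with a median of -0.041.

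Cholesterol synthesis genes were higher with Dyrk1a. Of 20 tested, 19 had a fitted log2 ratio above 0 and 11 were above 0 in all 5 arrays. The median was 0.18, a 1.13-fold higher level. The sterol demethylase gene Cyp51 was at 0.23 (SE 0.035) and Dhcr7, the enzyme of the last step to cholesterol, at 0.19 (SE 0.039). Adjusted over the list alone 13 rose, and over all genes 0. Camera's adjusted p was 6.11e-10, and the call was lost at adjusted p = 0.0886 with an estimated correlation. Fry's adjusted p was 0.00764. With Dyrk1a out of the lists that hold it, fry's adjusted p was 0.0573, 0.0511 and 0.0724 without replicate 1, 4 and 5. Without replicate 2, 6 members were higher over all genes in limma.

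A further question of the study concerned REST, a repressor of neuronal genes outside neurons, and its chromatin partners. REST-repressed neuronal genes were higher with Dyrk1a, with a median log2 ratio of 0.10 over 29 tested genes, 21 of them above 0. Their medians were 0.038 to 0.12 in the 5 arrays, and the fitted median was 0.064 without replicate 2. The secretory granule genes Chga, at 0.16 (SE 0.032), and Chgb, at 0.21 (SE 0.042), had the smallest p. Chgb was at 0.49, 0.34 and 0.46 with Dyrk1a in Cy5 and at -0.071 and 0.058 with it in Cy3, with a dye effect of 0.22 (limma adjusted p = 0.0649). Adjusted over the list alone 9 rose, and over all genes 0. Camera's adjusted p was 0.000121 (adjusted p = 0.0970 with an estimated correlation) and fry's 0.00688. With Dyrk1a out of the lists that hold it, fry's call was lost without replicate 4 (adjusted p = 0.0613) and without replicate 5 (adjusted p = 0.0746). The list of neuronal cytoskeleton and growth cone was higher as well, with a median of 0.083 over 27 genes, 22 above 0, and of 0.055 without replicate 2. Stmn4, a stathmin, was at 0.39 (SE 0.059), and Gap43, of growing axon tips, at 0.22 (SE 0.034). Adjusted over the list alone 3 rose, which were these genes and the neuronal tubulin gene Tubb3 at 0.25, named after its values were seen, and over all genes 0. Camera's adjusted p was 0.000215 (adjusted p = 0.0970 with an estimated correlation) and fry's 0.00688. Without replicate 4 or 5, and with Dyrk1a out of the lists that hold it, fry gave this list an adjusted p of 0.117 or 0.134. Fry's mixed test without replicate 4 or 5, with Dyrk1a kept in those lists, gave an adjusted p of 0.315 or 0.0691. Tubb3 belongs to both neuronal lists.

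Members of the REST complex did not pass as a list. The median over 17 tested genes was 0.0073 with a mean of -0.0088, and camera, whose direction was lower, gave an adjusted p of 0.838. With 1 array left out the median ran from -0.011 to 0.004. Rest was at -0.041 (95% interval -0.14 to 0.057), Rcor1 at 0.073, Sin3a at -0.063 and Hdac1 at 0.0080. Without replicate 2 Rest was at -0.065, Rcor1 at 0.035 and Hdac1 at 0.0028. Hmg20b, a subunit of the CoREST complex, was at -0.31 (SE 0.097), lower in 4 of 5 arrays and not past the threshold (limma adjusted p = 0.312). Without replicate 2 it was at -0.39 and passed, with a limma adjusted p of 0.0435. Ehmt1 was at -0.14, and at -0.055 without replicate 2. The SWI/SNF complex had a median of -0.0094 over 24 genes and a camera adjusted p of 0.332. Bcl7a was at -0.11 and Pbrm1 at -0.10. Array weights brought this list past the threshold with a median of -0.034 (adjusted p = 0.512 with an estimated correlation), and with 1 array left out its median ran from -0.021 to 0.016.

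**Figure D2:**
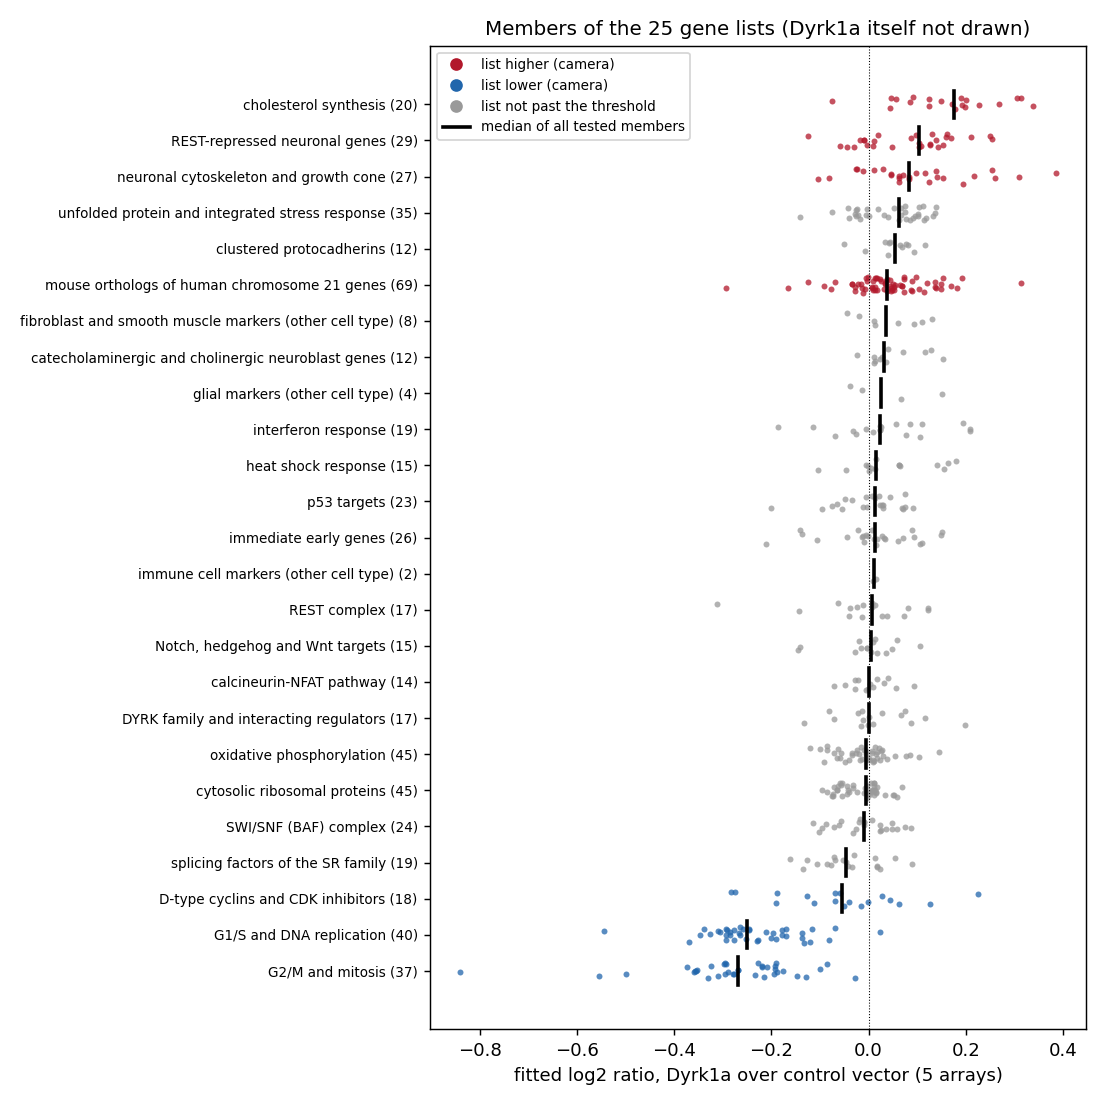
Fitted log2 ratio of Dyrk1a over control vector (horizontal axis) for each tested member (points) of the 25 gene lists, with the number of tested members in brackets and the list's median as a black bar; colour gives the camera result at the preset correlation, and Dyrk1a itself is not drawn. The mitosis and DNA replication lists have medians of -0.27 and -0.25, and cholesterol synthesis has the highest at 0.18.

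Mouse orthologs of human chromosome 21 genes, the chromosome that carries DYRK1A in humans, had a median log2 ratio of 0.038 over 69 genes, 51 of them above 0. Camera's adjusted p was 0.00610 (adjusted p = 0.108 with an estimated correlation), and 0.0157 with Dyrk1a taken out of the list. Without Dyrk1a fry gave 0.0395, and 0.0513 to 0.352 with 1 array left out. Apart from Dyrk1a 0 members passed over all genes. Adjusted over the list alone Dyrk1a rose and Chaf1b, a chromatin assembly gene that is also in the replication list, fell by 0.29. Chaf1b was named after its values were seen. The DYRK family and its regulators had a median of 0.00050 over 17 genes and a camera adjusted p of 0.368. The list holds the virus-delivered Dyrk1a. With Dyrk1a taken out the median was -0.001, camera's adjusted p 0.876 and that of fry's mixed test 0.257. With 1 array left out and Dyrk1a in the list the median ran from 0.003 to 0.01. Dyrk1a and Ywhag, a 14-3-3 gene at 0.20 named after its values were seen, rose adjusted over the list alone.

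**Figure D3:**
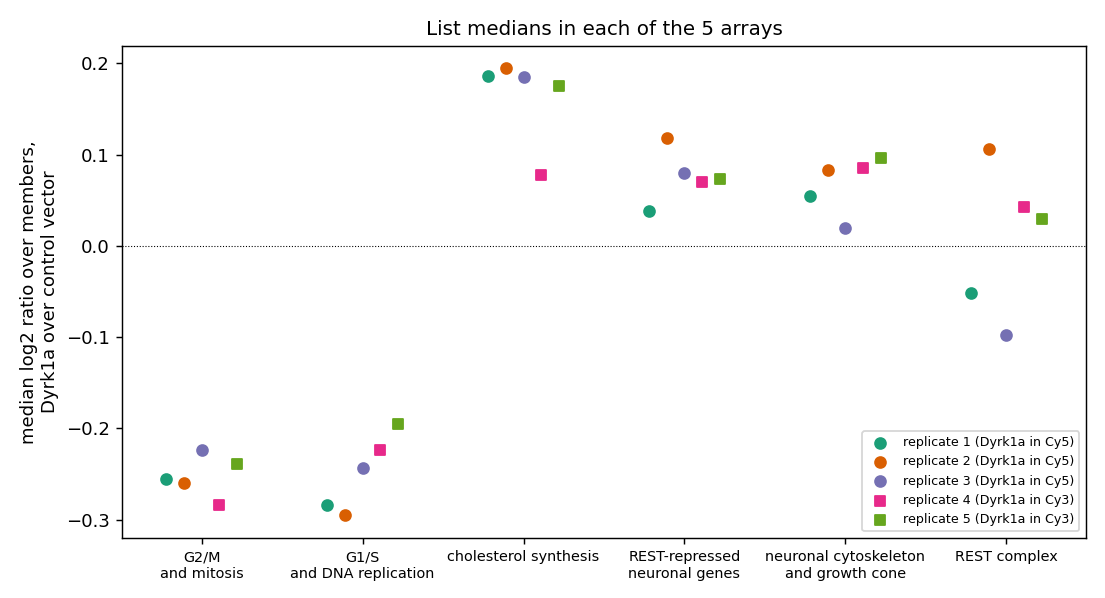
Median log2 ratio of Dyrk1a over control vector over the tested members of 6 gene lists (vertical axis) in each of the 5 arrays (points; circles with Dyrk1a in Cy5, squares with Dyrk1a in Cy3). The mitosis medians run from -0.28 to -0.22 and the replication medians from -0.30 to -0.19, below 0 in both orientations, while the REST complex lies on both sides of 0.

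Clustered protocadherins had a median of 0.054 over 12 genes, with Pcdhga7 at 0.082 and Pcdha6 at 0.12, or 0.17 without replicate 2. Fry's adjusted p was 0.00764 but camera's was 0.0786 (adjusted p = 0.338 with an estimated correlation). With Dyrk1a out of the lists that hold it, fry's was 0.0839, 0.098, 0.193 and 0.134 without replicate 1, 3, 4 and 5. Camera passed without replicate 2 (adjusted p = 0.0252), with a median of 0.055, but not there with the correlation estimated (adjusted p = 0.393 with an estimated correlation). Without replicate 1 the median was 0.034. By array the medians were 0.082, 0.088 and 0.074 with Dyrk1a in Cy5 and 0.0055 and -0.0080 with it in Cy3, and on the dye term fry gave an adjusted p of 0.0263, and 0.103 to 0.661 with 1 array left out. Camera did not pass on that term (adjusted p = 0.572, and adjusted p = 0.795 with an estimated correlation). Genes of the unfolded protein response had a median of 0.062 over 35 genes, with Hspa5 at 0.14 and Ddit3 at 0.11, and a camera adjusted p of 0.0776. Their median was 0.011 without replicate 2, and the list passed without replicate 5, with a median of 0.064 (adjusted p = 0.446 with an estimated correlation). SR splicing factors had a median of -0.046 over 19 genes, with Srsf10 at -0.11 and Srsf5 at -0.13, and a camera adjusted p of 0.0592 (adjusted p = 0.367 with an estimated correlation). This list passed without replicate 2, with a median of -0.027 and a camera adjusted p of 0.00812 (adjusted p = 0.413 with an estimated correlation). It also passed without replicate 5, with a median of -0.051 (adjusted p = 0.446 with an estimated correlation). Catecholaminergic and cholinergic neuroblast genes had a median of 0.031 over 12 genes (camera adjusted p = 0.232), with Alk at 0.12 and Phox2a at 0.15. Phox2a was at 0.642 in replicate 2 and at 0.042 in the fit without it. Without replicate 4 the list's median was 0.059 and Alk was at 0.068.

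The interferon list, relevant to cells carrying virus on both sides of the comparison, had a median of 0.024 over 19 genes (camera adjusted p = 0.297). Fry's mixed test passed, with an adjusted p of 0.0147, but not without replicate 3, 4 or 5, with 0.0572, 0.76 and 0.0691. Ifi35 rose by 0.21 and Cxcl10 fell by 0.19 adjusted over the list alone, and over all genes 0 members passed. Immediate early genes had a median of 0.013 over 26 genes and a camera adjusted p of 0.914, while fry's mixed test gave an adjusted p of 0.00141, and 0.76 without replicate 4. Arc fell by 0.21 adjusted over the list alone, over all genes 0 passed, and Ier5 was at -0.14. The p53 targets had a median of 0.013 and a mean of -0.00060 over 23 genes, with camera's direction lower (adjusted p = 0.914), Psrc1 at -0.20 and Trp53inp1 at -0.096. The median was 0.001 without replicate 2. Heat shock genes had a median of 0.016 over 15 genes (camera adjusted p = 0.389), with Hspb8 at 0.16 and Hsp90aa1 at -0.10. Without replicate 2 these were 0.042, 0.10 and -0.056. Calcineurin-NFAT genes had a median of 0.0010 and a mean of 0.0034 over 14 genes with camera's direction lower (adjusted p = 0.914), Rcan3 at 0.094 and Il2 at -0.072, or -0.037 without replicate 5. Notch, hedgehog and Wnt targets had a median of 0.0059 and a mean of -0.0039 over 15 genes with camera's direction lower (adjusted p = 0.876), Hes5 at -0.14 and Lgr5 at -0.14. Oxidative phosphorylation had a median of -0.0058 over 45 genes (camera adjusted p = 0.427), with Cox7c at -0.12 and Uqcrfs1 at -0.091. With 1 array left out the medians ran from -0.013 to 0.019 for calcineurin-NFAT, from -0.002 to 0.026 for Notch, hedgehog and Wnt targets, from -0.02 to 0.004 for oxidative phosphorylation and from 0.005 to 0.017 for immediate early genes.

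Markers of other cell types were thinly measured. Glial markers had a median of 0.026 over 4 genes (camera adjusted p = 0.427), with Cnp at 0.067 and Pmp22, which alone rose adjusted over the list alone, at 0.15. The median was -0.013 without replicate 5, and Cnp was at 0.043 without replicate 2. Fibroblast and smooth muscle markers had a median of 0.036 over 8 genes (camera adjusted p = 0.629), with Pdgfrb at 0.13 and Fbln1 at 0.060. The median turned to -0.029 without replicate 2, Pdgfrb was at 0.076 without replicate 4 and Fbln1 at 0.038 without replicate 3. Immune markers had a median of 0.012 over 2 genes (camera adjusted p = 0.914), Fcer1g at 0.015 and Cd3e at 0.0089. With 1 array left out the median ran from -0.024 to 0.049, Fcer1g from -0.041 to 0.072 and Cd3e from -0.021 to 0.074.

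The dye effect was of the size of the Dyrk1a effect. Its SD over genes was 0.088 against 0.091, and 149 genes had a dye effect in limma, 52 brighter in Cy5 and 97 in Cy3. Of 45 cytosolic ribosomal protein genes 39 had a dye effect below 0, with a median of -0.13, and 10 passed over all genes. On the dye term, in tests chosen after seeing the data, camera's adjusted p was 5.05e-17 (adjusted p = 0.681 with an estimated correlation). Fry's was 0.0263, and 0.0875 to 0.327 with 1 array left out. The list's medians by array were -0.089, -0.21 and -0.16 with Dyrk1a in Cy5 and 0.15 and 0.10 with it in Cy3. Rplp1 and Rplp2 had dye effects of -0.47 and -0.53 (limma adjusted p = 0.00300 and 0.00185), and fitted Dyrk1a changes of -0.071 and -0.065. The list's fitted median was -0.0061 over 45 genes, with a camera adjusted p of 0.232, and turned to 0.003 with scaling and 0.009 with quantile normalization. It passed without replicate 1, with a median of -0.021 (adjusted p = 0.562 with an estimated correlation), and without replicate 4, with a median of -0.019 (adjusted p = 0.526 with an estimated correlation). The number of genes with a dye effect was 6, 1091, 48, 5 and 6 without replicate 1, 2, 3, 4 and 5. Of the 57 named genes other than Dyrk1a, 11 had a dye effect at least as large as their fitted change, among them Chgb, Ehmt1, Bcl7a, Ier5, Il2 and Pcdhga7. Between arrays, the correlation across named probes measured in all 5 arrays ran from -0.0050 to 0.639 for pairs of the same orientation and from -0.177 to 0.062 for pairs of opposite orientation.

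Whether genes that lie side by side moved together was tested on 10940 adjacent pairs. The change had the same sign in 53.6% of pairs, against a mean of 50.5% over 10000 random orders of the genes. The one-sided permutation p was 1e-04, the smallest that 10000 random orders can give. With pairs of like symbols left out the share was 53.5%. Without replicate 2 the share was 51.4% against 50.2%, with a one-sided permutation p of 0.0034. The number of adjacent pairs past the threshold in the same direction was 0 with all 5 arrays and 11 without replicate 2, a count not set against random orders.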

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

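The tests of the dye, of other arrays left out, of like symbols and of replicate 2 in the cell-cycle lists were chosen after their results were seen. For the others, what each outcome would mean was written down before the result was seen. Tests of an antiviral response and of random lists, which bear on the cell-cycle lists, are given under the other observations. Among 86 sets of 5 array values, 9 held an array far from the other 4 by Dixon's gap ratio, where chance gives about 1 in 20, here 4.3. Replicate 2 was that array in 4 of the 9, replicate 3 in 3 and replicate 4 in 2.

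Replicate 2 stood apart in the interquartile range over genes, at 0.288, in the median of the glial list, at 0.132, in Phox2a, at 0.642, and in Cd3e, at -0.303. Replicate 3 stood apart in Lmnb1, at -0.32, Trp53inp1, at 0.063, and Pmp22, at 0.018. Replicate 4 stood apart in the median of cholesterol synthesis, at 0.078, and in Dhcr7, at 0.056.

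The first pattern is that far more genes passed the threshold without replicate 2, 329, than with all 5 arrays, 1. Fewer arrays do not account for it, since leaving out any other array gave at most 1 gene. Among the genes called without replicate 2, its values rose with those predicted from the other 4 arrays with a slope of 0.744. The sign was the same in 76.3% of these genes. The bootstrap 95% interval of the slope, 0.571 to 0.891, describes replicate 2 alone and leaves out the spread between arrays. The called genes include the virus-delivered Dyrk1a, at 2.30 in replicate 2, and the slope was not computed without it. Whether a dye effect shared with other arrays of the same orientation adds to the slope was not tested. The slope and the shared signs leave open that replicate 2 carried part of the same response. The slope lies below 1, but the genes were chosen on the 4 arrays that gave the predicted values. Such a choice can lower a slope, so its distance from 1 decides nothing. However, the 5 H4 histone genes had a median of 0.57 in replicate 2 against -0.89 to -0.37 in the other arrays. The deviations of replicate 2 had the same sign in 54.3% of adjacent pairs of genes, so they are not independent noise. Why replicate 2 differed was not tested.

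Other splits of the arrays' signs were too few to give a share under 0.05. Of 15 splits of 5 arrays, 4 gave at least the 1 gene of the real one, and the highest other gave 1369. That split sets replicates 1 and 3 against 2, 4 and 5, and with the dye term it gives replicate 2 a term of its own. Its count points to a structure of the arrays, since the tested term is then a difference between the dye effect of the other 4 arrays and the value in replicate 2, so its calls mix both, and no test here separates them. At an unadjusted p under 0.05 it gave 3329 genes against 1301 for the real split. Of 7 splits of the 4 arrays without replicate 2, 1, the real one with 329 genes, gave as many, and the highest other gave 6.

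The second pattern is the lower level of the DNA replication and mitosis lists. A dye effect would turn their sign between orientations, but the highest median of either list in any array was -0.195. Noise in replicate 2 would not carry to the other arrays, and without it the higher of both medians was -0.244. A lower share of dividing cells with Dyrk1a is a candidate explanation that no test here addresses. A difference in virus dose or in cell density between the arms cannot be separated from Dyrk1a by the 5 arrays, and stays open as well.

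The third pattern is the excess of neighbours with the same sign. Regional properties of the probes that act through the dyes would show in the dye effect. Its same-sign share was 50.5%, inside its random range of 49.7% to 51.5%. Replicate 2 enters the dye effect with the same weight as the Dyrk1a effect, yet its deviations, given below, did not show there. Why they did not was not tested. The dye effect therefore cannot exclude regional effects in single arrays. Like symbols left out gave 53.5%, above the random range. Noise of replicate 2 as the whole cause is set against a share of 51.4% without it, above a random range that ends at 51.1%. It may be part of the cause. The deviations of replicate 2 from the values predicted by the other 4 arrays had the same sign in 54.3% of adjacent pairs. Their random range was 49.1% to 50.9%. The excess was smaller without replicate 2, but the dye effect, in which replicate 2 weighs as much, showed none. How much of the excess comes from replicate 2 is therefore open. The 1.27 percentage points that remain without it are a hypothesis for further arrays.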

How the results depend on the processing

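Averaging whichever probes were measured, leaving Dyrk1a out of its lists, the list tests on 4 arrays, the estimated correlation with array weights, fry's mixed test without each array, the list tests on the dye term and the arrays left out of the dye and neighbour results were chosen after seeing the data. Of the alternatives tried 0 reversed a result past the threshold, but the medians of 10 of the 18 lists not past it changed sign in at least 1. The causes of the changes below were not tested unless given. Genes higher and lower numbered 1 and 0 as reported. They were 43 and 175 with arrays scaled to 1 spread, 47 and 190 with quantile normalization, 622 and 717 with array weights, 7 and 68 with only named genes tested (fewer features to adjust for), and 15 and 100 at adjusted p under 0.10. Turning the swapped arrays back gave 52 and 97, which by construction are the dye effects. The count higher was 0 at adjusted p under 0.01, without moderation, and over features in at least 4 arrays. Leaving out 1 array gave 0 to 81 higher and 0 to 248 lower, both upper ends without replicate 2. Dyrk1a ranged from 1.29 to 2.54 with 1 array left out, and lost its call without replicate 1, 4 or 5. In the last case a further probe had entered its mean. The dye effect count ranged from 5 to 1091, highest without replicate 2. The same-sign share of neighbours stayed past its threshold in all alternatives run.

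Of the 25 lists 7 passed, and 0 with an estimated correlation, with 5 arrays, without each array in turn and with array weights. Camera then takes its degrees of freedom from the residuals, which few arrays limit strongly. For REST-repressed neuronal genes the estimated correlation was -0.025, below the preset 0.01, yet camera's unadjusted p went from 1.94e-05 to 0.0169. It was 0.045 for mitosis and 0.071 for replication. A lost call therefore cannot be put down to correlation between members alone. Fry passed 7 with 5 arrays, 6 of them shared with camera and protocadherins in place of D-type cyclins, and 7 without replicate 2. Without replicate 4 or 5, and with Dyrk1a out of its lists, only the mitosis list passed fry (adjusted p = 0.0027 and 0.000647). Fry's mixed test passed 10, of which 6 passed without each array in turn. A pair of these 6 holds the virus-delivered Dyrk1a, and with it taken out the numbers were 9 and 3. On the dye term camera passed 2, ribosomal proteins and oxidative phosphorylation, fry 4, these with protocadherins and p53 targets, and 0 passed with an estimated correlation. With 1 array left out fry passed 0 on that term, except p53 targets without replicate 3, and camera 2 or 3. Leaving out some array moved 19 of the 25 medians by over 1.5 times, 2 of them of lists past the threshold, and 13 of the 57 named genes other than Dyrk1a. Medians of lists that crossed the threshold were -0.034 for SWI/SNF with array weights, 0.058 and 0.066 for protocadherins with array weights and with single probes, and -0.024 for D-type cyclins over features in at least 4 arrays. They were 0.053 and 0.057 for the unfolded protein response with scaling and quantile normalization, and for SR factors -0.055, -0.058, -0.053 and -0.065 with scaling, quantile normalization, array weights and single probes. With 1 array left out the ranges were 0.034 to 0.055 for protocadherins, -0.053 to -0.037 for D-type cyclins, 0.011 to 0.072 for the unfolded protein response, -0.055 to -0.025 for SR factors and -0.021 to -0.001 for ribosomal proteins. The 57 genes kept their direction wherever called. Of them 39 passed the threshold with array weights, 23 without replicate 2, 21 with scaling, 20 with quantile normalization, 15 with named genes only and 3 with the swapped arrays turned back. With no intensities used here, what signal over background limits is unknown.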

Other observations

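The results here were chosen after the data were seen, except the test of random lists on centred values in the last paragraph, whose outcomes were set out before it was run. Genes whose symbols share the letters before the first digit were tested as families, 335 of them with at least 5 tested genes. By limma's camera 9 families were lower and 2 higher, and 0 with an estimated correlation, where the lowest adjusted p was 0.964. That version rests on the few residual degrees of freedom, so it says little about the 335 families. The Smc family, which holds the ATPase subunits of cohesin and condensin, was below 0 in 6 of 6 genes with a median log2 ratio of -0.18 (camera adjusted p = 8.42e-06). The Haus family, of the augmin complex on the mitotic spindle, was below 0 in 7 of 8 genes with a median of -0.17 (camera adjusted p = 8.42e-06). Rfc clamp loader genes were below 0 in 5 of 5, with a median of -0.25, and 3 of them are in the replication list. Centrosomal Cep genes were below 0 in 28 of 32 with a median of -0.071 (camera adjusted p = 1.39e-05), and nucleoporin Nup genes in 13 of 18 with a median of -0.068 (camera adjusted p = 0.00206). The Gstm family of glutathione transferases was above 0 in 7 of 7 genes with a median of 0.10 (camera adjusted p = 0.00701), although probes of such close paralogs can share signal. Collagen genes, symbols starting with Col, were above 0 in 17 of 19 with a median of 0.083 (camera adjusted p = 0.0303), which was 0.041 without replicate 2. These families kept the sign of their medians with scaling, with quantile normalization and without centring.

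Of the 248 genes lower without replicate 2, 57 belonged to the replication or mitosis lists and 191 to neither. Among those with the largest falls, Cenpf was at -0.78 and Cenpe at -0.53, both kinetochore genes. The condensin gene Smc4 was at -0.52, the chromatin gene Dek at -0.48 and Max, the partner of Myc, at -0.54. With all 5 arrays these genes had limma adjusted p of 0.0724, 0.0605, 0.0762, 0.0831 and 0.115. Among those with the largest rises were Stmn4 at 0.43, Angpt2, an angiopoietin gene, at 0.38, and the lipid droplet gene Plin3 at 0.35. With all 5 arrays these had limma adjusted p of 0.0905, 0.171 and 0.406, and Plin3, at -0.205 in replicate 2, was at 0.26.

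Histone cluster genes differed between arrays. The 5 tested H4 genes had medians of -0.37, -0.89, -0.49 and -0.38 in replicates 1, 3, 4 and 5 and of 0.57 in replicate 2, where 4 of the 5 were above 0. The 7 tested H2A genes had a median of -0.32 in replicate 2 and of -0.46, -0.54, -0.23 and -0.24 in the others. The 6 tested H2B genes had medians of -0.012, -0.155, 0.002, -0.196 and -0.138 in replicates 1 to 5, and 1 of them was lower without replicate 2. The 2 tested H3 genes had medians of -0.24, -0.54, -0.36, 0.092 and 0.12, and 0 were lower. The 5 tested H1 genes had medians of -0.11, -0.032, -0.16, -0.30 and -0.34. In replicate 2, 3 of them were below 0 and 2 above, H1f4 at 0.72 and H1f5 at 0.58. H1f4 and H1f5 were below 0 in each of the other arrays. Of 25 histone cluster genes 14 were lower without replicate 2 in limma, and 0 with all 5 arrays, where at an unadjusted p under 0.05 all genes together numbered 1301. Probes of these near-identical genes can share signal, so the genes are not separate measurements. The difference between replicate 2 and the other arrays was not tested.

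A hypothesis for the higher REST-repressed neuronal genes was a lower level of Rest mRNA. Rest was at -0.041 with a 95% interval of -0.14 to 0.057, which includes both no change and a fall of 0.10, and at -0.065 without replicate 2, so the 5 arrays could not decide it. The fitted Rest probes had means of 0.03 and -0.05. A further Rest probe, outside the fit, had deposited values of -1.334, 0.027, 0.564 and 0.216 in replicates 2 to 5. A change in REST protein was not measured.

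A pair of further explanations of the lower replication and mitosis lists was tested. A difference in the cells' antiviral response to the viruses was read from the interferon list, whose mean log2 change was 0.038 with a bootstrap 95% interval over its genes of -0.0080 to 0.083. That interval lies within 0.1 of 0, the bound set for excluding it. The bound was too weak, since the interval leaves out the spread between arrays and the members went both ways, 5 above 0.1 and 2 below -0.1. Fry's mixed test, for changes in either direction, passed for the interferon list at an adjusted p of 0.0147, so its members are not shown to be unchanged, and this explanation stays open. A shift of all probes was set against 10000 random lists of 37 genes, of which 0 had a median as low as the mitosis list and the lowest was at -0.046. Without centring the mitosis and replication lists had medians of -0.263 and -0.244 against 0.013 over all genes, and 0 of 10000 random lists came as low, the lowest being at -0.041 and -0.038. The lists were thus lower than other genes, which a shift of all probes alike cannot give. The median over all genes was near 0 with and without centring, so random lists had to lie near 0. The comparison therefore repeats what camera tests and is not separate evidence.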
